A study of Mus musculus with 4 samples.

How the data were processed

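RNA of pancreatic islets was measured on 4 Agilent mouse expression arrays of a single colour, each hybridised with Cy3-labelled material of 1 mouse. Per the labels, 2 arrays held islets of mice with the Pdx1-Cre transgene alone, called control here, and 2 held islets of Pdx1-Cre mice with floxed Rb alleles, called Rb-deficient here. Pdx1-Cre deletes floxed sequence in cells of the pancreatic lineage. Per the labels' protocols, RNA was taken up with an RNeasy kit and amplified and labelled with the Ovation Pico WTA System. The group and replicate number of each array came from the sample titles.

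The deposited scanner files hold intensity values per spot. Per the file headers, Agilent Feature Extraction 12.0.3.1 read all arrays with a protocol for a single colour, and the processed intensity is background-subtracted and spatially detrended, with no scaling between arrays. Per the file headers, the probe design was annotated on the mm9 mouse build. All 4 arrays shared 1 slide, so slide and scan were the same for both groups and a fit with slide as a block could not be made. Each array held 62976 spots, of which 59305 were not controls, for 56605 probes. No spot was saturated on any array.

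A deposited value table of the whole series was set against the scanner files. For each array its intensity values were the processed signal times a constant, 2.44 and 2.15 for the control arrays and 2.49 and 1.74 for the Rb-deficient arrays. The scale was thus linear, genes were not centred, and direction does not arise for a single colour. Which statistic set the constants, and by which rule its 48058 features were chosen, stays unknown. The column medians were 220.06, 180.7, 188.3 and 157.33 in the same order. The table was used as an alternative only.

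The files give an accession but no gene symbol per probe. Accessions were matched without versions to a RefSeq gene table of the GRCm38.p6 assembly, which named 32994 of 56605 probes, 58.3%, with 22911 symbols. Probes without a match kept the name in the file. Gene coordinates are not printed, because that assembly differs from the build of the design.

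For the main analysis, control spots and spots with an outlier mark (64 to 93 per array) were left out. Values were log2 of the processed signal minus the array's 75th percentile over non-control probes, and spots of a probe were averaged. A probe was kept when it was well above background on both arrays of at least 1 group, which left 33848 probes. Of several probes of a gene, 5951 genes in all, the one with the highest mean signal over the 4 arrays was used. This gave 26378 genes, a count that includes unnamed transcripts and 15826 genes with a symbol.

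Rb-deficient and control islets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are Rb-deficient minus control on the log2 scale. With 2 against 2 arrays, the smallest two-sided p an exact permutation test of a single value can give is 0.333, so no such test was used. The number of arrays limits the precision, and limma had 2 residual degrees of freedom per gene and a prior worth 1.82.

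Where a probe was not well above background on either array of a group, only a bound is given, as "at least N-fold". It is the brighter group's mean against a floor for the dimmer group, taken on each array as the lowest signal of any probe well above background there or the probe's own signal if higher. That this is judged on the probe used, and not on all probes of the gene, was settled after the data were seen. Of the genes tested, 494 had such a probe in Rb-deficient islets and 91 in control islets.

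Gene lists were fixed before the data were examined, 17 of pathways and gene classes and 13 of cell type or sex markers. The 29 lists other than the sex-linked genes were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 29. Camera with an estimated correlation and fry were run as alternatives. Lists overlap in a few genes, most of all the G1/S list and the list of the pocket protein, E2F and cyclin D pathway, which share 5.

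The rule for named genes was also fixed before the data were examined. It takes Rb1 and, in each direction, the 8 called genes with a symbol and the largest change whose Rb-deficient values both lie beyond both control values, filled up with the smallest p values where fewer were called. It adds at most 4 called members of each list, or the 2 with the smallest p where none was called, and lets the text name fewer. The values of 1 gene that the rule takes are not reported here. Which of these list members are named was settled after their values were seen. Genes outside the rule are said to have been chosen after their values were seen.

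The alternatives fixed in advance were normexp background correction with an offset of 50, quantile normalization, scaling to the array median, the deposited value table, no filter on dim probes, a filter for signal on all arrays, marked spots kept, eBayes with a trend or robust, the mean of a gene's probes, each probe on its own, an added fold threshold of 2, the replicate number as a block and each array left out in turn. The column of mean signal that normexp was to use is not among the columns of the files used here, and the median spot signal and median background took its place. None was added later. The slide as a block was listed too and was not run, as all arrays share 1 slide.

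The procedure was tested on simulated data with the spread of these arrays, 26378 genes and 200 of them changed. At a log2 change of 1 or 2 no gene was called. At a change of 3, 91 genes were called, 86 of them among the 200. With the median SD given to every gene, 99 of the 200 were called at a change of 1 and 200 at a change of 2 or 3. In 20 draws of the 29 lists, 2 unchanged lists were called in all, and a list shifted by 0.5 on the log2 scale was called in 20 of 20. In camera with an estimated correlation the shifted list had an unadjusted p under 0.05 in 19 of 20. On the measured arrays the lowest such p was 0.080, for the p53 targets. The draws may thus lack the correlation between genes of these arrays, and they do not give the error rate of camera's preset correlation on them.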

Results

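The series asked how gene expression in mouse pancreatic islets differs when the retinoblastoma gene Rb1 is deleted in the pancreatic lineage. Islets are the endocrine clusters of the pancreas, made up of insulin-producing beta cells with alpha, delta and other hormone cells. Islets of 2 Rb-deficient mice and of 2 control mice carrying only the Cre transgene were each measured on 1 array. Well above background were 76.5% of probes on control array 1 and 59.4% on control array 2, against 59.9% and 59.0% on Rb-deficient arrays 1 and 2. The 75th percentile of processed signal was 361 and 411 intensity units on the control arrays and 364 and 488 on the Rb-deficient arrays. Across genes, which are not independent replicates, Pearson's r between pairs of arrays lay between 0.951 and 0.979.

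The arrays also differed in sex-linked transcripts. On control array 1 the Y-linked genes Eif2s3y, Kdm5d, Ddx3y and Uty had log2 signals of 1.15, -1.73, -2.06 and -2.13 relative to the 75th percentile, and on the other 3 arrays no probe of these genes was well above background. Xist, the RNA of the inactive X chromosome, lay at -7.40 on control array 1, not well above background, and at -0.84, -0.65 and -1.35 on control array 2 and the Rb-deficient arrays. Probes for olfactory, vomeronasal and taste receptors, 1421 in all, were well above background in 37.9% of cases on control array 1 and in 13.1% to 14.4% on the others. The control mean therefore joins arrays that differ in sex-linked transcripts and in the share of probes with signal. The sample titles give no sex. By the Y-linked and Xist signals, control array 1 held a male and the other arrays females, so sex was not balanced between the groups.

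**Figure D1:**
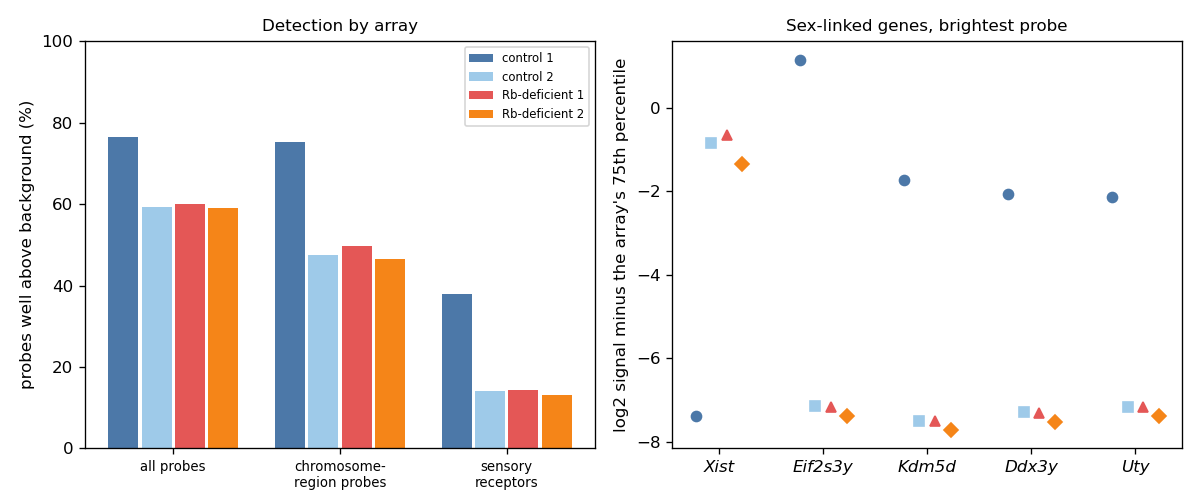
Percentage of probes well above background on each of the 4 arrays, for all probes, probes designed to chromosome regions and probes for sensory receptors (left), and log2 signal relative to the array's 75th percentile for Xist and 4 Y-linked genes, 1 point per array (right). Control array 1 has the highest share in each class, 37.9% for sensory receptors, and is the array with Y-linked signal.

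Rb1, the deleted gene, had a log2 signal of 0.57 ± 0.41 (SD, n = 2) in control islets and -0.69 ± 0.30 (SD, n = 2) in Rb-deficient islets. The difference was -1.26 with a standard error of 0.31, which is 2.40-fold lower. Both Rb-deficient arrays lay below both controls. A second Rb1 probe was 2.94-fold lower, with -2.23 and -2.11 on the control arrays and -3.35 and -4.10 on the Rb-deficient arrays. In limma with Benjamini-Hochberg adjustment over all genes the adjusted p of the first probe was 0.735, so the difference was not called. Whether either probe lies in the deleted part of the gene is not known here, so the values do not by themselves check the genotype.

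No gene passed the threshold. Among 26378 genes limma called 0, the lowest adjusted p (Benjamini-Hochberg) was 0.163, and 1493 had an unadjusted p under 0.05, 390 higher and 1103 lower in Rb-deficient islets, where 1318.9 were expected by chance. The ranges of the groups did not overlap for 9502 genes, or 36.0%, where chance gives 33.3%, and 4032 of these were higher in Rb-deficient islets and 5470 lower. At least 2-fold differences numbered 448 higher and 2119 lower. Without control array 2, limma called 4102 genes, 17 higher and 4085 lower, and 3858 of them had a probe above background on control array 1 alone. Scaling to the array median in place of the 75th percentile moved the median difference of all genes from -0.07 to 0.37, and limma then called 480 genes, 234 higher and 246 lower. That scaling adds a constant to every difference, so that the medians of gene lists given below stood higher by it, 1.27 in place of 0.83 for the G1/S list and -0.51 in place of -0.95 for the acinar list.

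The genes with the smallest p among those higher in Rb-deficient islets, given as values only, were led in size by Zfp423, which encodes a zinc finger transcription factor. Its log2 signal was -1.75 ± 0.67 (SD, n = 2) in control and 2.13 ± 0.54 (SD, n = 2) in Rb-deficient islets, a 14.8-fold difference, and its 2 probes differed by 3.68 and 3.88. Retnla, a secreted resistin-like protein of activated macrophages, was 7.86-fold higher. Col6a3, a collagen VI chain, was 6.81-fold, Fam199x 4.45-fold and the orphan receptor gene Gpr19 2.62-fold higher. For Klra16, Defb44-ps and the centromere protein gene Cenpu the probe was not well above background in control islets, and they were at least 2.85-fold, 2.25-fold and 1.99-fold higher. The probe of a gene was chosen anew in each setting, and in some another, brighter probe of Cenpu took the place of this one. The log2 difference of Cenpu was then -0.85 with dim probes kept, -1.90 without control array 2 and -0.62 without Rb-deficient array 1. The first probe did not reverse, with -6.0 and -5.9 on the control arrays and -4.4 and -4.1 on the Rb-deficient arrays. The probes of Cenpu thus disagreed.

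Of the genes lower in Rb-deficient islets, Rnf150, a ring finger protein gene, was measured on all arrays. It had a log2 signal of 0.43 ± 0.08 (SD, n = 2) in control and -3.32 ± 0.19 (SD, n = 2) in Rb-deficient islets, 13.4-fold lower. The probes of the other 7 genes were not well above background in Rb-deficient islets. Ubtfl1 was at least 6.16-fold, the glucuronyltransferase gene B3gat2 at least 5.71-fold and the smooth muscle calponin gene Cnn1 at least 4.25-fold lower. Serpina3c, the alcohol dehydrogenase gene Adh4, Pira2 and Ripor3 were at least 3.90-fold, 3.88-fold, 2.01-fold and 2.00-fold lower. In limma these 16 genes had adjusted p values (Benjamini-Hochberg) from 0.163 to 0.446.

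Genes of the cell division cycle had higher signal in Rb-deficient islets. The list of G1/S and DNA replication genes, known targets of the E2F transcription factors that Rb binds, rose, with 42 of 43 measured members higher and a median log2 difference of 0.83, a 1.78-fold change (camera, Benjamini-Hochberg adjusted p 1.2e-26; adjusted p = 0.558 with an estimated correlation). Its median was 0.60 above the control mean on Rb-deficient array 1 and 1.12 on array 2. Mcm3 and Mcm6, subunits of the replicative helicase, were 6.80-fold and 5.64-fold higher, with log2 differences of 2.77 and 2.50 and standard errors of 0.42 and 0.45. Their probes with the smallest differences gave 1.63 for Mcm3 and 1.82 for Mcm6. The G2/M and mitosis list rose too, with 34 of 37 members higher and a median of 1.36, or 1.35 with 3 dim genes at their bounds (camera, Benjamini-Hochberg adjusted p 5.7e-18; adjusted p = 0.558 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, was 5.57-fold higher with signal on 3 arrays, and Ect2, an exchange factor needed for cytokinesis, 2.73-fold. Mki67, which encodes the proliferation antigen Ki-67 and was chosen after its values were seen, was 4.91-fold higher.

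Neither call held with an estimated correlation. In limma no member of these lists was called over all genes, nor adjusted over the list alone, although 35 of the 43 G1/S members and 27 of the 37 G2/M members were above both controls on both Rb-deficient arrays. Without control array 1 the G1/S median was 0.89, with 42 of 43 higher. The G2/M median was 0.79 without control array 2, with 28 of 42 higher, and 0.58 with normexp background correction, and the list stayed past the test in both. On the same Rb-deficient arrays the acinar marker list lay 0.47 and 1.39 below the control mean in median and the macrophage list 0.33 and 1.36 above it.

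**Figure D2:**
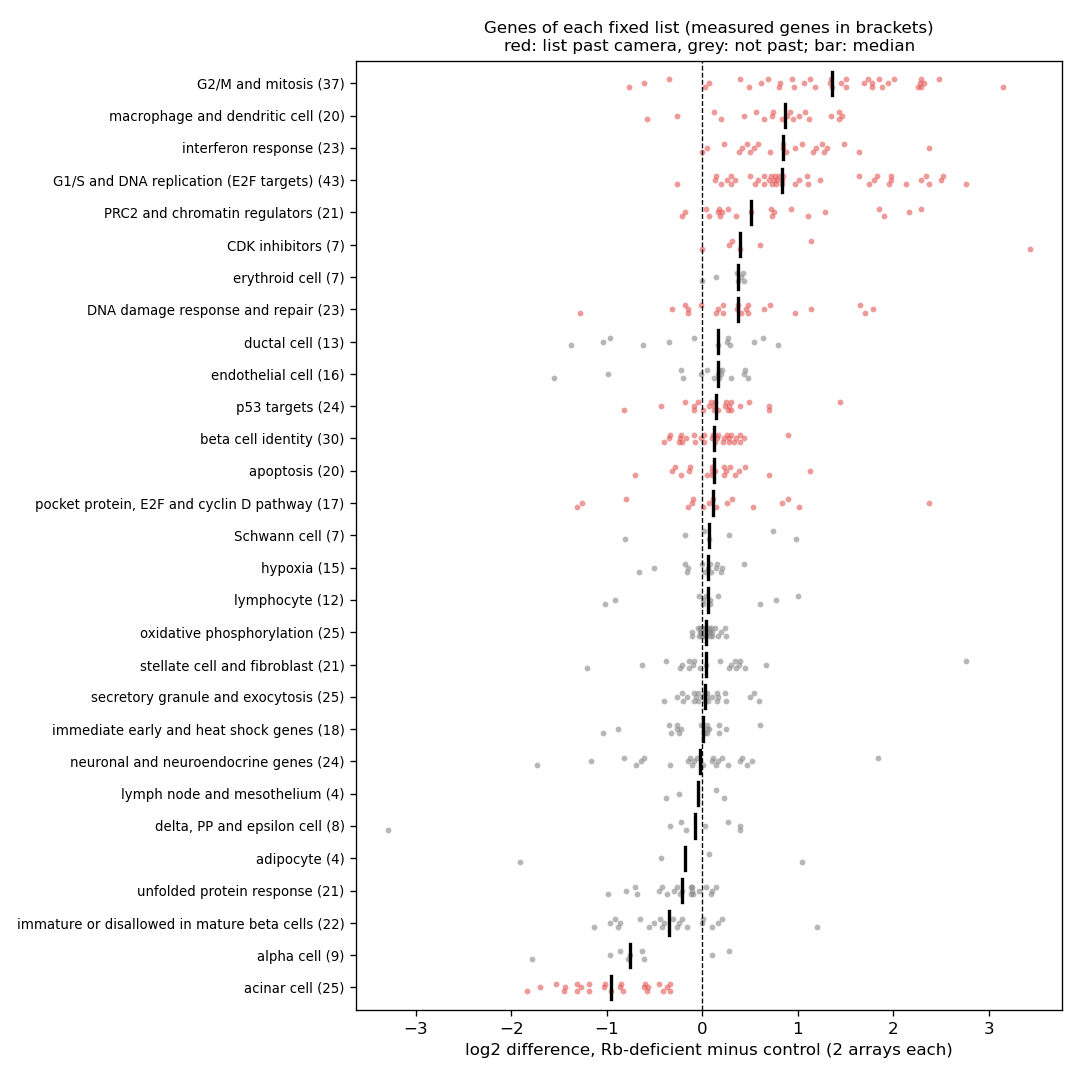
Log2 difference, Rb-deficient minus control, of every measured gene (1 point each) in 29 fixed lists, with the list median as a black bar and lists past camera at the preset correlation in red. The G1/S and G2/M lists have medians of 0.83 and 1.36, the acinar list -0.95.

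Members of the Rb pathway itself went both ways. The list of pocket proteins, E2F factors, D cyclins and their kinases passed camera with 11 of 17 members higher and a median of 0.11 (adjusted p 0.0327 with Benjamini-Hochberg adjustment; adjusted p = 0.558 with an estimated correlation). E2f1 was 2.03-fold and Cdk2 1.86-fold higher, while Rb1 was lower as above. Ccnd1 and Ccnd2, which encode cyclins D1 and D2 and were chosen after their values were seen, were 2.49-fold and 1.73-fold lower. Of its members, 5 are also in the G1/S list. The list missed the test in camera without control array 1 (adjusted p 0.11) and without Rb-deficient array 2 (adjusted p 0.30), and its median was 0.21 without Rb-deficient array 1. It also missed it with normexp, quantile normalization, median scaling, a filter for signal on all arrays and the replicate number as a block, at medians of 0.064, 0.16, 0.55, 0.090 and 0.11.

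Inhibitors of cyclin-dependent kinases rose, with 6 of 7 higher and a median of 0.40 (camera, Benjamini-Hochberg adjusted p 2.0e-04; adjusted p = 0.558 with an estimated correlation). Cdkn2a, the locus of the Ink4a and Arf proteins, had the largest difference. Its log2 signal was -3.09 ± 0.09 (SD, n = 2) in control islets and 0.34 ± 1.27 (SD, n = 2) in Rb-deficient islets, 10.8-fold higher, with -0.55 and 1.24 on the Rb-deficient arrays. Its 2 probes differed by 3.43 and 3.57. Cdkn2c, which encodes another Ink4 inhibitor, was 2.21-fold higher. Macrophage markers, 0.33 and 1.36 above the control mean, were also farther from it on Rb-deficient array 2. The list's median was 0.60 without control array 2, 0.66 without Rb-deficient array 1 and 0.65 when a gene's probes were averaged.

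**Figure D3:**
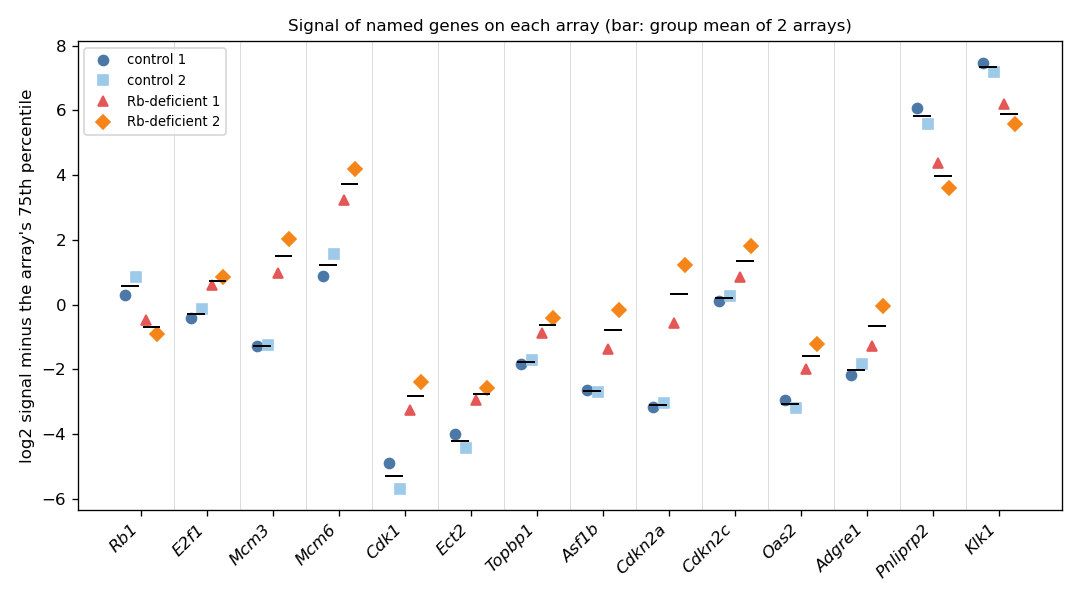
Log2 signal relative to the array's 75th percentile for 14 named genes, 1 point per array, with the group mean of 2 arrays as a bar. Rb1 lies lower on both Rb-deficient arrays than on both controls, and Mcm3, Mcm6, Cdk1 and Cdkn2a lie higher.

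The DNA damage response and repair list rose, with 17 of 23 higher and a median of 0.37 (camera, Benjamini-Hochberg adjusted p 7.2e-06). Its adjusted p = 0.558 with an estimated correlation. Topbp1, an activator of the ATR checkpoint kinase, was 2.20-fold higher. The list's median was 0.24 without control array 1 and 0.19 with normexp background correction. The list of PRC2 and chromatin regulators rose, with 19 of 21 higher and a median of 0.51 (camera, Benjamini-Hochberg adjusted p 4.1e-09). Its adjusted p = 0.558 with an estimated correlation. The members with the smallest p act in replication and mitosis rather than in PRC2. Asf1b, a histone chaperone, was 3.74-fold and Ncaph, a condensin subunit, 4.49-fold higher. The list's median was 0.31 without Rb-deficient array 2. The DNA damage list stood 0.27 and 0.47 above the control mean on the Rb-deficient arrays and the chromatin list 0.31 and 0.65, where the macrophage list stood at 0.33 and 1.36 and the acinar list at -0.47 and -1.39.

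Lists of p53 targets and of apoptosis genes passed camera with small medians. Of the p53 targets 18 of 24 were higher, with a median of 0.15 (Benjamini-Hochberg adjusted p 0.0091; adjusted p = 0.558 with an estimated correlation). Tnfrsf10b, a death receptor gene, was 2.72-fold higher, while its other probe differed by 0.15 on the log2 scale. Bax, a pro-apoptotic member of the Bcl-2 family, was 1.62-fold higher, with 0.27 on the log2 scale in its other probe. Of the apoptosis genes 14 of 20 were higher, with a median of 0.12 (camera, Benjamini-Hochberg adjusted p 0.0209; adjusted p = 0.558 with an estimated correlation). Trp73, the p53 relative, was 1.62-fold lower. Without Rb-deficient array 2 neither list passed camera, with adjusted p values (Benjamini-Hochberg) of 0.24 and 0.46, and the p53 target median was 0.039, against 0.24 without Rb-deficient array 1 and 0.34 without control array 1. The apoptosis list also missed it without control array 1 (adjusted p 0.15), its median was 0.18 without Rb-deficient array 1, and it turned to -0.13 and missed camera when a gene's probes were averaged (adjusted p 0.43). Both lists missed the test with quantile normalization, at medians of 0.17 and 0.095, and apoptosis with median scaling at 0.56.

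Genes of beta cell identity differed little. The list passed camera with 19 of 30 higher and a median of 0.12 (Benjamini-Hochberg adjusted p 0.0327; adjusted p = 0.795 with an estimated correlation). The insulin genes Ins1 and Ins2, chosen after their values were seen, were 1.17-fold and 1.16-fold lower, with log2 differences of -0.23 and -0.22 and standard errors of 0.25 and 0.26. Trpm5, a cation channel gene, was 1.86-fold higher, and Abcc8, the sulfonylurea receptor subunit of the ATP-sensitive potassium channel, was 1.32-fold lower, a difference that turned to 0.035 on the log2 scale with median scaling. The list's median was 0.18 above the control mean on Rb-deficient array 1 and -0.083 on array 2. It turned to -0.083 without Rb-deficient array 1, was 0.22 without control array 2 and, without control array 1, was 0.0071 with an adjusted p of 0.49 in camera. It missed the test with quantile normalization (0.13), median scaling (0.56) and a filter for signal on all arrays (0.12).

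Other lists of islet function and stress did not pass camera. Secretory granule genes had a median of 0.029 (adjusted p 0.115, Benjamini-Hochberg), with Ptprn, a granule membrane protein gene, 1.42-fold higher but at 0.018 on the log2 scale in its other probe. Genes immature or disallowed in mature beta cells had a median of -0.35 (camera adjusted p 0.172), with the Notch ligand homologue Dlk1 2.31-fold higher and the transcription factor gene Sox9 1.96-fold lower. Neuronal genes had a median of -0.024 (camera adjusted p 0.369), with Stmn1, a microtubule destabiliser, 3.58-fold higher and Mapt, the gene of tau, 1.56-fold lower. The unfolded protein response had a median of -0.21 (camera adjusted p 0.359), with Sel1l, of the ER degradation complex, 1.98-fold lower. Oxidative phosphorylation had a median of 0.035 (camera adjusted p 0.059), hypoxia 0.064 (0.371) with Higd1a 1.58-fold lower, and immediate early and heat shock genes 0.0061 (0.838) with the heat shock genes Hspa1b and Hspa1a 2.05-fold and 1.84-fold lower. The medians of the immature, neuronal and unfolded protein lists were above 0 with median scaling, that of the neuronal list also with normexp and quantile normalization, and that of the immediate early list was below 0 with these 2. With an array left out, some passed camera, the secretory list without control array 2 (0.040) or Rb-deficient array 2 (0.088), the immature list without Rb-deficient array 2 (-0.49, against -0.14 without control array 1 and -0.099 without Rb-deficient array 1) and the unfolded protein list without Rb-deficient array 1 (-0.45). Without control array 2 the neuronal, oxidative phosphorylation and immediate early lists passed upward although their medians were -0.015, -0.0069 and -0.028. Camera sets a list against the other genes, and the median of all genes in that fit was -0.38. These passes, and that of the secretory list without control array 2, therefore do not show that the lists rose.

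Interferon response genes rose, all 23 measured members being higher in mean, with a median of 0.84 (camera, Benjamini-Hochberg adjusted p 7.8e-10; adjusted p = 0.558 with an estimated correlation). Oas2, an antiviral oligoadenylate synthetase, was 2.79-fold and Rsad2, the gene of viperin, 2.48-fold higher. The shift was uneven between mice, with a median of 0.20 on Rb-deficient array 1 and 1.34 on array 2. Macrophage and dendritic cell markers rose in the same uneven way, with 18 of 20 higher, a median of 0.86 and shifts of 0.33 and 1.36 (camera, Benjamini-Hochberg adjusted p 4.3e-08; adjusted p = 0.558 with an estimated correlation). Adgre1, the gene of a macrophage surface receptor, was 2.54-fold and Fcer1g, an Fc receptor subunit, 1.66-fold higher. Both lists stayed past camera without Rb-deficient array 2, with medians of 0.20 and 0.33, against 1.34 and 1.36 without Rb-deficient array 1. With normexp background correction the interferon median was 0.48.

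Markers of acinar cells, the enzyme-secreting exocrine cells around islets, fell, with 25 of 25 lower and a median of -0.95 (camera, Benjamini-Hochberg adjusted p 4.1e-09; adjusted p = 0.571 with an estimated correlation). Pnliprp2, a pancreatic lipase-related gene, had a log2 signal of 5.82 ± 0.36 (SD, n = 2) in control and 3.99 ± 0.55 (SD, n = 2) in Rb-deficient islets, 3.56-fold lower, and the kallikrein gene Klk1 was 2.72-fold lower. The median was -0.47 on Rb-deficient array 1 and -1.39 on array 2, and -0.47 in the fit without array 2. The list missed camera without control array 2, when its median was -1.09 and that of all genes was -0.38.

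**Figure D4:**
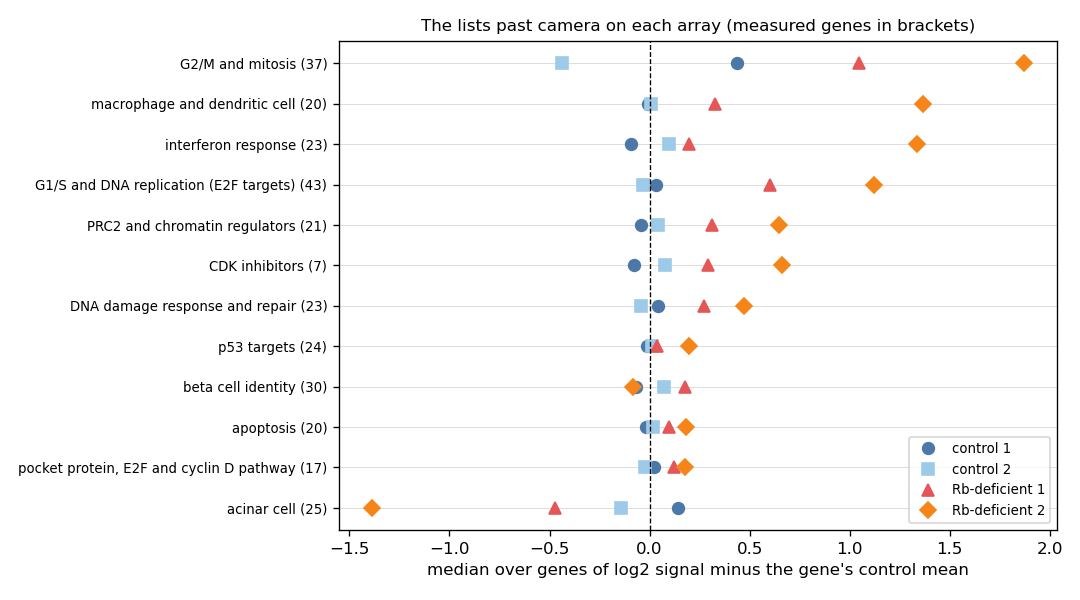
Median, over the genes of each of the 12 lists past camera, of log2 signal minus the gene's control mean, 1 point per array. Rb-deficient array 2 lies farther from 0 than array 1 for the macrophage (1.36 against 0.33), interferon (1.34 against 0.20) and acinar (-1.39 against -0.47) lists.

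Markers of the remaining cell types did not pass camera. Alpha cell markers had a median of -0.75, with 7 of 9 lower (Benjamini-Hochberg adjusted p 0.0507), the transcription factor gene Irx2 1.95-fold and the transthyretin gene Ttr 1.69-fold lower, with -0.39 on the log2 scale in its other probe. They passed camera without control array 1 (adjusted p 0.033), with normexp (0.0083), with quantile normalization (0.0073) and with a filter for signal on all arrays (0.026), at medians of -0.76, -0.71, -0.67 and -0.75. The list stood at -0.48 and -1.10 on the Rb-deficient arrays, and without array 2 its median was -0.48 and it did not pass (adjusted p 0.092). Delta, PP and epsilon cell markers had a median of -0.072, which was above 0 with quantile normalization and median scaling, with Ghrl, the ghrelin gene, 9.76-fold lower but with a control SD of 2.15 and probes between -5.64 and -3.29. Ductal markers had a median of 0.17, which was -0.059 with normexp, with the mucin gene Muc1 2.60-fold lower. Endothelial markers had a median of 0.17 and stellate cell and fibroblast markers 0.035 (camera, both adjusted p 0.0507). Without control array 2 or Rb-deficient array 1 both passed, at 0.051 and 0.35 for endothelial and 0.29 and 0.58 for stellate markers. The median of all genes was -0.38 and -0.08 in those fits. Without Rb-deficient array 2 the stellate list passed downward, with 16 of 21 lower and a median of -0.51 (adjusted p 0.0136). The stellate list had -0.51 and 0.58 on the Rb-deficient arrays and held the single gene called when adjusted over the list alone, Col6a3.

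Lymphocyte markers had a median of 0.060, with 9 of 12 higher and the T cell receptor subunit gene Cd3d 1.88-fold lower. Ptprc, the gene of the leukocyte common antigen, was 2.01-fold higher in the probe used, at -1.43 on the log2 scale in its other probe and at -0.21 in the mean of both. Medians were 0.37 for erythroid, -0.18 for adipocyte, 0.073 for Schwann cell and -0.048 for lymph node and mesothelium markers. The adipocyte median was above 0 with median scaling and the lymph node median with normexp, quantile normalization and median scaling. Camera's adjusted p values (Benjamini-Hochberg) for these lists lay above the threshold, and the erythroid list passed without control array 1 or Rb-deficient array 1, at medians of 1.19 and 0.92, and the Schwann cell list without Rb-deficient array 1, at 0.40. In the hypoxia, neuronal, immediate early, delta cell, ductal and endothelial lists the median, the mean and the direction of the test did not all have the same sign. Of the 29 lists 12 passed camera, 11 of them upward, and 0 passed with an estimated correlation or with fry, whose lowest adjusted p was 0.511.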

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

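All tests in this part were chosen after the result was seen, except that the test of genomic DNA was set before its result was known.

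Signal in probes that the main comparison left out, though some alternatives used them, stood out on control array 1. The Y-linked genes Eif2s3y, Kdm5d, Ddx3y and Uty had log2 signals of 1.15, -1.73, -2.06 and -2.13 there in their brightest probes, which were not well above background on any of the other 3 arrays. That array also had 9682 of the 22757 probes left out of the main comparison well above background, against 408, 1157 and 1317 on control array 2 and Rb-deficient arrays 1 and 2. Both are signals of a control sample, set against the other arrays, because no sample outside the groups exists to serve as a blank. The other control array does not share them, so sex and array cannot be separated from a single mouse.

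As the source of the extra dim signal of control array 1, scanner or non-specific background did not show in the negative control spots. Their median after background subtraction was -1 intensity unit there and up to 1 on the other arrays. This argues against signal above local background that all spots share, and leaves non-specific binding to the gene probes alone open. Template from genes that islets do not transcribe stays open, as sensory receptor probes were above background in 37.9% of cases there and at most 14.4% elsewhere, but any source of extra dim signal would raise that share. For genomic DNA of the male mouse, probes for chromosome regions that were dark on the other arrays were used. Their ratio of X to autosomal medians was 1.12 (95% bootstrap interval 0.806 to 1.48), while a single X would lower it. The lower limit lies only just above the bound set for this test. The probes were not required to have signal on control array 1, where 75.2% of all region probes were well above background. Probes near background would hide a lower dose of X, so the test cannot decide and genomic DNA stays open. Sex of the mouse, unspliced or intergenic RNA, a longer amplification and other differences of the mouse were not tested and stay open.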

How the results depend on the processing

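Every alternative named here was fixed before the data were examined. The 0 genes called by limma held in all settings but 2, with 1016 to 3823 genes in the others at an unadjusted p under 0.05. With median scaling 480 genes were called, 234 higher and 246 lower. There limma's estimated prior gave every gene a common spread in place of a prior worth 1.82 degrees of freedom, and the median difference of all genes moved from -0.07 to 0.37, since that scaling adds a constant to every difference. Without 1 array at a time 0 to 4102 genes were called, 0 to 17 higher and 0 to 4085 lower. The 4102 came without control array 2, and 3858 of them, 94.1%, had a probe above background on control array 1 alone. Each probe on its own and an added fold threshold called 0. Rb1 was lower in every setting, from -1.55 to -0.83 on the log2 scale, the smallest with median scaling, and was not called. Signal over background limits these arrays, since the filter on dim probes set how many genes were tested, 23946 with signal on all arrays and 45611 without a filter.

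The 2 groups share replicate numbers, which nothing shows to pair mice. Differences between replicates correlated at r = 0.295 across genes over only 2 pairs. With the number as a block 0 genes were called, 13 lists passed, the pocket protein list, median 0.11, missed the test at an adjusted p of 0.0501 in camera, and the endothelial and stellate lists passed it. The block changed no other call.

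Lists past camera numbered 12 in the main analysis and 9 to 17 in the settings that kept camera's preset correlation. With an estimated correlation, and with fry, 0 lists passed, and the medians stayed as they were, 0.83 for G1/S, 1.36 for G2/M, 0.11 for the pocket protein list, 0.40 for inhibitors of cyclin-dependent kinases, 0.15 for p53 targets, 0.12 for apoptosis, 0.37 for DNA damage, 0.51 for chromatin regulators, 0.12 for beta cell identity, 0.84 for interferon, -0.95 for acinar and 0.86 for macrophage markers. The pocket protein list missed the test with normexp (0.064), quantile normalization (0.16), median scaling (0.55) and a filter for signal on all arrays (0.090). The p53 targets missed it with quantile normalization (0.17), apoptosis with quantile normalization (0.095) and median scaling (0.56), and beta cell identity with quantile normalization (0.13), median scaling (0.56) and the filter for all arrays (0.12). Apoptosis turned to -0.13 and missed the test when a gene's probes were averaged. The constant of median scaling, added to all genes alike, raises the medians there but was not shown to account for the lost calls. The cause of these changes was not tested.

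Leaving out an array, medians ranged from 0.082 to 0.21 for the pocket protein list, 0.096 to 0.18 for apoptosis, -0.083 to 0.22 for beta cell identity, 0.039 to 0.34 for p53 targets and -1.39 to -0.47 for acinar markers, each of which lost its call in at least 1 of the 4 fits. A fit that leaves a lone array in a group assumes that it varies like the other group. In the fit without control array 2 the median of all genes, against which camera sets a list, was -0.38. The G1/S, G2/M, inhibitor, DNA damage, chromatin, interferon and macrophage lists stayed past camera in all settings with the preset correlation.

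Lists that were not past camera, and single genes, changed sign or side of the test as follows. With normexp the medians were 0.042 for neuronal, -0.019 for immediate early, -0.059 for ductal and 0.011 for lymph node genes. With quantile normalization they were 0.024 for neuronal, -0.0014 for immediate early, 0.29 for delta cell and 0.36 for lymph node genes. With median scaling they were 0.087 for immature, 0.41 for neuronal, 0.23 for unfolded protein, 0.37 for delta cell, 0.26 for adipocyte and 0.39 for lymph node genes, and Abcc8 lay at 0.035. With the filter for all arrays they were 0.055 for neuronal and 0.072 for adipocyte genes. With the mean of a gene's probes they were -0.025 for secretory, -0.0053 for hypoxia, -0.0086 for immediate early, -0.087 for ductal and -0.028 for stellate genes, and Ptprc lay at -0.21. Without a filter Cenpu lay at -0.85, in another probe than that of the main analysis. Leaving out an array gave -0.029 to 0.088 for secretory, -0.49 to -0.099 for immature, -0.053 to 0.10 for neuronal, -0.48 to 0.078 for unfolded protein, -0.12 to -0.028 for immediate early, -0.0069 to 0.058 for oxidative phosphorylation, -0.041 to 0.15 for hypoxia, -0.16 to 0.16 for delta cell, -0.24 to 0.22 for ductal, -0.035 to 0.35 for endothelial, -0.51 to 0.58 for stellate, -0.24 to 0.33 for lymphocyte, -0.37 to 1.19 for erythroid, -1.74 to 0.0034 for adipocyte and -0.021 to 0.40 for Schwann cell genes, -1.90 to 1.71 for Cenpu and -0.16 to 6.40 for Xist. The 6.40 is set against control array 1 alone, where the probe was not well above background, so it is no measured size. The 1.71 of Cenpu is no measured size either, being set against control array 2 alone, where its probe was not well above background. The -1.90 of Cenpu comes from another probe than the 1.71. Lists that passed only under an alternative with all arrays, at medians of their main sign, were alpha, endothelial and stellate markers and oxidative phosphorylation in several, and secretory and neuronal genes without a filter. There the neuronal list passed upward although its median was -0.024, where that of all genes was -0.24. Of the named genes, 28 were called in their main direction with median scaling, and some without control array 2. Genes that changed sign were left out of this count.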

Other observations

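The gene families in the next paragraph and the tests of the cell cycle pattern were chosen after the results were seen, while the test of Rb-deficient array 2 alone was set before its result was known but after the list medians per array had been seen.

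Families defined by their symbols gave groups that moved in Rb-deficient islets, some of which share genes with the fixed lists. Among others, Cenpa, Cenpe and Cenpf are also in the G2/M list, Cxcl10 in the interferon list, Cxcl12 in the immature list and Ccl19 in the lymph node list. The G1/S list holds the DNA polymerase genes Pola1, Pole and Pold1, and the interferon list the guanylate-binding protein genes Gbp2 and Gbp3. These families are thus not independent of the fixed lists. Of 13 families tested with camera and Benjamini-Hochberg adjustment over the 13, centromere proteins rose, with 18 of 21 higher and a median log2 difference of 0.47 (adjusted p 9.3e-08; adjusted p = 0.580 with an estimated correlation). DNA polymerases rose, with 12 of 13 higher and a median of 0.50 (camera adjusted p 2.3e-06; adjusted p = 0.580 with an estimated correlation). Genes of the major histocompatibility complex rose, with 19 of 25 higher and a median of 0.27, and chemokines rose, with 14 of 18 higher and a median of 0.62 (camera, both adjusted p 1.4e-04; both adjusted p = 0.580 with an estimated correlation). The medians of these 4 families were above 0 with quantile normalization too, and with normexp they were 0.26, 0.23, 0.29 and 0.31 in the order given. Chemokines shifted by 0.12 on Rb-deficient array 1 and 1.40 on array 2, where macrophage markers shifted by 0.33 and 1.36 and histocompatibility genes by 0.13 and 0.47. Chemokines had an adjusted p of 0.38 in camera without array 2. Histocompatibility genes had a median of 0.13 and an adjusted p of 0.10 without that array, while centromere proteins and DNA polymerases stayed past the test at 0.28 and 0.30.

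Guanylate-binding protein genes had a median of 0.51 (camera adjusted p 0.046; adjusted p = 0.580 with an estimated correlation), which shifted by 0.13 and 0.95 on the Rb-deficient arrays and missed the test without array 2 (adjusted p 0.60) and without control array 1 (adjusted p 0.45). Their median was 0.25 with normexp. Keratins and cytochrome P450 genes had medians of -0.24 (camera adjusted p 0.028 and 0.046; adjusted p = 0.580 and 0.617 with an estimated correlation), both above 0 with median scaling and at -0.055 and -0.010 with quantile normalization. Keratins were at -0.13 without control array 1 and -0.15 without Rb-deficient array 2, and the P450 genes missed the test without control array 1 and without Rb-deficient array 2. Replication-dependent histones had a median of 0.083 (camera adjusted p 0.106), cytosolic ribosomal proteins of -0.034 and kinesins of 0.0017. Collagens had -0.11, the Reg family -0.059 and Fanconi anemia genes -0.054, and none of these 6 families passed camera at the preset correlation. The histones changed sign without control array 1 (-0.061) and the others under a scaling or background alternative. The Reg family passed without control array 1 (-1.11), and collagens (-0.44) and ribosomal proteins (-0.16) without Rb-deficient array 2.

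The higher cell cycle lists were weighed against 3 technical explanations. The rise did not rest on control array 1, which had the extra dim signal. The G1/S median was 0.89 without that array and 0.83 with it, and the G2/M median 2.03 and 1.36. Signal added to these genes on a control array would lower their difference, so the comparison is only a weak test of this explanation. Less acinar RNA in the Rb-deficient samples would lift genes of all islet cells alike. Yet the G1/S median exceeded that of beta cell identity by 0.71 (95% bootstrap interval 0.54 to 1.09). Only beta cell identity stood for islet cells in this test. The medians of alpha cell markers and of delta, PP and epsilon cell markers were -0.75 and -0.072. The bootstrap intervals in this paragraph were drawn over genes, not mice. They carry no spread between mice and treat genes as independent. More immune cells in the Rb-deficient samples stay open, because macrophage markers were shifted by 0.33 (95% bootstrap interval 0.19 to 0.45) on Rb-deficient array 1 and by 1.36 (1.03 to 1.81) on array 2, and dividing immune cells could add cell cycle transcripts. Loss of Rb in islet cells, the difference the design names, is an open hypothesis too, and the arrays do not show which cells hold the transcripts.

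The higher interferon and macrophage lists and the lower acinar list were tested against Rb-deficient replicate 2 alone as their source. Without that array 3 of the 3 lists stayed past camera at the preset correlation, with medians of 0.20, 0.33 and -0.47. Replicate 2 may thus account for most of their size. That fit leaves a single Rb-deficient mouse, so it cannot tell a difference between the groups from a difference between individual mice. With an estimated correlation none of the 3 was called even with all arrays, at adjusted p = 0.558, 0.558 and 0.571. How much exocrine tissue was carried along in each islet preparation is not given in the sources used here. A difference in dissection, a response of the tissue to Rb loss and a difference between individual mice therefore stay open and untested.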
